A study of Mus musculus with 6 samples.

How the data were processed

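Libraries of poly(A) RNA were made from mouse myotubes with an Illumina TruSeq kit after Trizol extraction, per the labels' protocols. The 6 samples were placed in 2 groups of 3 by their labels, Ad-GFP and Ad-Zfp697, and the replicate numbers are those in the labels. The authors deposited a table of raw counts of reads per gene, which per the file headers was made with featureCounts 2.0.3 on the Ensembl release 102 annotation of GRCm38. Per the file headers, reads were counted without regard to strand and without the options that count multi-mapped reads or reads over several genes, so genes with near-identical copies or overlapping neighbours lose reads. The submitters' processing notes name STAR 2.7.3a, featureCounts 2.0.3, Subread, DESeq2 and the assembly GRCm38.p6.

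The authors also deposited a table of their own comparison, with log2 fold changes and p-values. 100% of its p-values lay within 1% of those of an unshrunken DESeq2 Wald test run here on the deposited counts. The deposited log2 fold changes were smaller than the unshrunken ones, by a median ratio of 0.0316 in the lowest of 4 equal classes of genes by mean and 0.948 in the highest, so they appear to have been shrunken. Its mean normalized signal per gene, the mean over all libraries that DESeq2 gives, was computed by the authors and served here only to form those classes. Gene positions in that table equal those of the count table for only 611 genes, so only positions from the count table are given, 1-based on GRCm38. Gene symbols came from the deposited table for 28642 genes and from GENCODE mouse release 21 for a further 26571.

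Every one of the 6 count columns matched a sample. Total counts per library ran from 19870911 to 35700170, and the 10 most abundant genes held 8.54% to 9.01% of reads. Libraries of one group differed by more than sampling noise (chi-square per degree of freedom 3.77 to 6.06 over genes with at least 10 counts in the pair), so no library was counted as deposited more than once. CPM here are counts relative to library totals scaled by the trimmed mean of M-values (TMM).

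The test of Ad-Zfp697 against Ad-GFP was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3, glmQLFit with robust estimation) on the deposited counts, with the group as the only term, after filterByExpr had left 16116 of 55487 genes; 23009 genes had no count in any library. Adjusted p-values are Benjamini-Hochberg over all genes tested, with a threshold of 0.05, and "called", "rose" and "fell" refer to it. Standard errors of log2 fold changes are the coefficient over the square root of F. The common biological coefficient of variation was 4.78%. The edgeR log2 fold changes used its default prior count.

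Before the data were examined, 40 lists with 773 genes were written, the alternatives below were listed, and the rule for named genes was set. The rule takes Zfp697, the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 1, no overlap between the groups and a symbol other than Gm with digits or one ending in Rik, and up to 4 members of each list with the smallest adjusted p. Further members of a list are named where its account needs them, and were chosen after their values were seen. All 773 listed genes were found in the count table. The 38 lists with at least 5 tested genes were compared with the other genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the lists. Camera called 5 lists. With a correlation estimated for each list it called 0, and 3 lists then had an unadjusted p under 0.05. In that setting the test rests on the 4 residual degrees of freedom, which leaves it little power after adjustment over the lists. Counts "adjusted over the list alone" adjust the gene p-values within that list.

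The alternatives were DESeq2 1.42.0, limma-voom, relative log expression, upper-quartile or no scaling beyond library totals, scaling without the Zfp697 gene, other filters and dispersion estimates, a replicate block, and leaving out each library. For the lists they were an estimated correlation and fry. The procedure was tested on simulated counts for 15847 genes with the means and library sizes of these samples: of genes changed 2-fold 88% were recovered, of those changed 4-fold 100%, and of those raised or lowered 1.5-fold 78% and 66.0%. Of 179 calls, 15 (8.38%) were on unchanged genes, and camera called the planted list, all of whose genes were raised 2-fold, and 0 of 20 random lists. The simulated genes were drawn independently of each other. False calls of lists with correlated members could therefore not appear. At most 50 tested genes were changed at each fold, while 55.0% of tested genes were called in the data. The adjustment depends on that share, so the recovered percentages need not hold for the data.

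Mitochondrial transcripts of GENCODE mouse release 21 were compared with all other transcripts of that release by blastn 2.17.0 at an identity of at least 95%. Reads of the adenovirus or of GFP are not analysed here. Results for some genes are not reported here.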

Results

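Gene expression was measured by poly(A) RNA sequencing in primary mouse myotubes, the multinucleated muscle cells that form in culture when satellite cells, the stem cells of skeletal muscle, differentiate and fuse. The cells came from C57BL/6 mice and were differentiated in medium with 5% horse serum. They were then exposed overnight, at a multiplicity of infection of 100, to an adenovirus that carried either the mouse gene Zfp697 (Ad-Zfp697) or green fluorescent protein (Ad-GFP). Each virus had 3 libraries, 6 in all, and the single comparison of the design was Ad-Zfp697 against Ad-GFP. The series title describes Zfp697 as an RNA-binding protein that regulates inflammation and remodeling of skeletal muscle, and the comparison asks which transcripts differ when myotubes carry more of it. Reads assigned to genes numbered 29716752, 28047755 and 35700170 in Ad-GFP replicates 1 to 3 and 28800325, 19870911 and 31813774 in Ad-Zfp697 replicates 1 to 3. Nothing in the labels says that the replicates were separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical. Each group had its own virus, and no library without virus or at another dose was analysed. Every change given below as with Zfp697 may therefore also come from another difference between the viruses.

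Zfp697 itself was first examined in each library. Its count was 998, 943 and 1100 in the Ad-GFP libraries and 659706, 463524 and 824500 in the Ad-Zfp697 libraries. The mean level was 33.2 ± 1.54 CPM (read counts scaled to library size; SD, n = 3) with Ad-GFP and 23681 ± 1529 CPM (SD, n = 3) with Ad-Zfp697, a log2 fold change of 9.48 (SE 0.07, adjusted p = 2.93e-37). The gene (ENSMUSG00000050064) lies on chromosome 3 from 98382461 to 98753812 on the plus strand of GRCm38, and its count adds reads of the endogenous and of the viral transcript where both match its exons. The lowest share among the control libraries was 0.00308% of assigned reads (95% Clopper-Pearson interval 0.00290 to 0.00327) in Ad-GFP replicate 3. The highest was 2.59% (interval 2.59 to 2.60) in Ad-Zfp697 replicate 3. Such intervals cover counting error only. Every library therefore matched its label at the delivered gene.

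With Zfp697, most listed genes induced by interferon rose and most listed genes of the sarcomere fell, with the counts and list tests given below. Iigp1, an interferon-induced GTPase that acts against intracellular pathogens, went from 2.76 ± 0.190 to 51 ± 5.52 CPM (SD, n = 3), a log2 fold change of 4.2 (SE 0.10, adjusted p = 1.35e-23), the largest rise after Zfp697 among the genes that the fixed rule considered. Ckm, the creatine kinase of muscle that buffers ATP during contraction, went from 801 ± 51.1 to 61.8 ± 5.99 CPM (SD, n = 3), a log2 fold change of -3.70 (SE 0.06, adjusted p = 3.60e-24), the largest fall under that rule. The myosin heavy chain genes Myh2, Myh3 and Myh1, and Myog, the transcription factor that drives terminal myoblast differentiation, also fell, as given below for their groups.

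**Figure D1:**
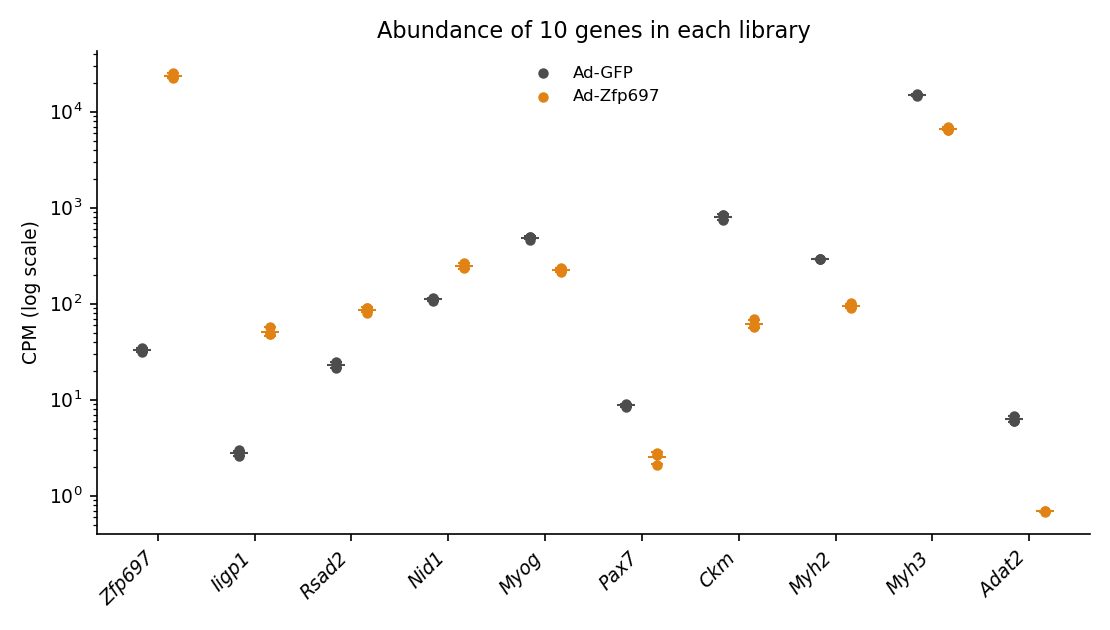
CPM (log scale) of 10 genes in each of the 6 libraries; grey points are Ad-GFP and orange points Ad-Zfp697, and the dash and bars are the mean and SD of 3 libraries. Iigp1 rose from 2.76 to 51 CPM and Ckm fell from 801 to 61.8 CPM.

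The test covered 16116 of 55487 annotated genes, and 8865 of them (55.0%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test. Of these, 4547 were higher and 4318 lower with Zfp697. At least 2-fold changes numbered 1025 higher and 577 lower. The latter counts depended on how many scarce genes entered the test: with no filter on low counts they were 1544 and 749, and with at least 50 counts in 3 libraries 422 and 294. On log2 CPM the first principal component held 72.7% of the variance and separated the groups. The second held 10.3% and spread the Ad-Zfp697 libraries, with replicate 2 at -27.7 and replicates 1 and 3 at 20.5 and 8.98. On it the Ad-GFP libraries lay between -1.81 and 0.755. Pearson's r across genes, which are not independent replicates, was 0.991 to 0.995 between libraries of one group and 0.971 to 0.976 between libraries of different groups.

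**Figure D2:**
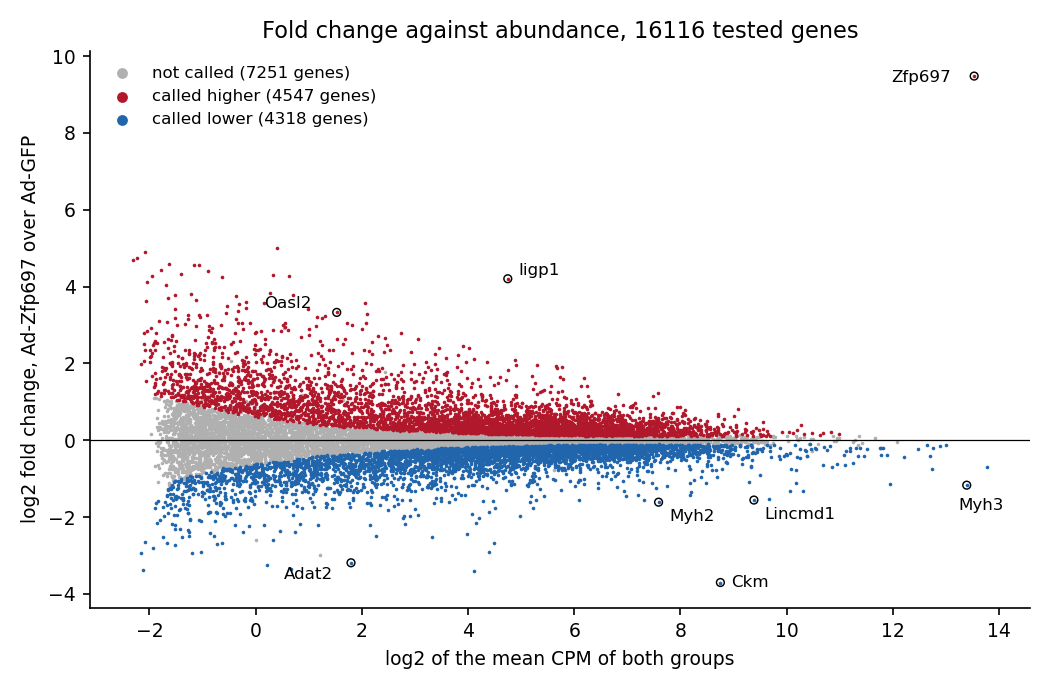
Log2 fold change, Ad-Zfp697 over Ad-GFP, against the log2 of the mean CPM of both groups, 1 point for each of 16116 tested genes. Red points are the 4547 genes called higher, blue points the 4318 called lower, and grey points those not called; Zfp697 stands at 9.48, Iigp1 at 4.2 and Ckm at -3.70.

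Interferon-stimulated genes had the largest median change of the 40 lists: 29 of 30 tested members rose, over all genes tested and likewise 29 adjusted over the list alone, with a median log2 fold change of 1.91. Rsad2 (viperin, an enzyme that blocks viral RNA synthesis) rose from 23.1 ± 1.75 to 86.7 ± 5.16 CPM (SD, n = 3), a log2 fold change of 1.91 (SE 0.06, adjusted p = 2.33e-20). Oasl1 rose with a log2 fold change of 2.41 (SE 0.09, adjusted p = 1.30e-19), and Ifit1, which binds foreign 5' ends of RNA, with 1.96 (SE 0.07, adjusted p = 2.87e-19). The exception was Irf7, at a log2 fold change of 0.08 (adjusted p = 0.722). Stat2 and Irf9, which form the transcription factor downstream of the type I interferon receptor, rose by 1.01 and 0.91 on the log2 scale, and the sensors of viral RNA Ifih1 and Rigi by 1.08 and 1.16. The list passed limma's camera test against all other genes (adjusted p = 1.35e-11; adjusted p = 0.462 with an estimated correlation). Camera also called it in each of the other splits of the 6 libraries into 3 and 3, with adjusted p from 1.74e-05 to 0.0111. Those splits mixed both viruses unevenly on each side. Part of the difference between the viruses therefore remained, and these calls do not show that the list passes without it.

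Genes of MHC class I antigen presentation rose less: 10 of 12, also 10 adjusted over the list alone, with a median log2 fold change of 0.66. They included Tapbp, which loads peptide onto class I molecules (0.94, SE 0.06, adjusted p = 4.51e-14), the class I heavy chain H2-K1 (0.57, SE 0.05, adjusted p = 1.51e-10) and B2m, the light chain (0.41, SE 0.05, adjusted p = 1.60e-08). H2-K1 shares reads with close paralogs, and reads that mapped to several places were not counted, so its level is uncertain. The list passed camera (adjusted p = 0.000754; adjusted p = 0.462 with an estimated correlation). Of the complement and acute phase genes 6 of 7 rose, 6 also adjusted over the list alone, without passing as a list (adjusted p = 0.0828). C3, the central component of the cascade, rose from 0.233 ± 0.0537 to 3.04 ± 1.45 CPM (SD, n = 3), and Masp1 rose by 0.27 on the log2 scale.

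Other inflammatory groups were mixed or scarcely expressed. Only 3 of 22 chemokine genes were abundant enough to test; Cxcl10, an interferon-induced chemokine, rose from 0.390 ± 0.167 to 1.19 ± 0.188 CPM (SD, n = 3; adjusted p = 8.12e-05), while Cx3cl1 and Cxcl12 had log2 fold changes of 0.02 and 0.00. Among 13 tested cytokines 7 rose and 2 fell (7 and 3 adjusted over the list alone); Tnfsf15 rose by 2.64 on the log2 scale and Il15 fell by 1.13 (list adjusted p = 0.344). Of 18 genes of the NF-kB pathway and its targets 8 rose and 4 fell (9 and 4 adjusted over the list alone), with Rela at 0.59 and Tnfaip3, an inhibitor of the pathway, at -0.58 (list adjusted p = 0.362).

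Macrophage and leukocyte markers moved in the direction of these immune genes, most of them at low levels. Of 7 tested markers 5 rose (5 adjusted over the list alone), among them Mrc1, the mannose receptor, from 18.1 to 30.3 CPM (adjusted p = 2.58e-09), Cd74 from 0.409 to 1.97 CPM, Cd68 from 0.653 to 2.39 CPM and Mpeg1 from 0.237 to 0.913 CPM. The list did not pass camera (adjusted p = 0.0791), but did without Ad-GFP replicate 2 (adjusted p = 0.0458). Ptprc, the common leukocyte antigen, had 4 counts over the 3 Ad-GFP libraries and 8 over the 3 Ad-Zfp697 libraries, and Tyrobp had 0 in all 6, which at a floor of 3 counts leaves lower levels undetectable at this depth.

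Sarcomere genes fell as a group. Of 35 tested members 27 fell and 1 rose, the same numbers adjusted over the list alone, with a median log2 fold change of -0.38. The camera test gave an adjusted p of 1.34e-06 (adjusted p = 0.491 with an estimated correlation). The fall differed between myosin heavy chains. Myh2, the chain of fast oxidative fibres, fell from 290 ± 0.631 to 95.1 ± 4.86 CPM (SD, n = 3; log2 fold change -1.61, SE 0.05, adjusted p = 4.36e-21). The embryonic chain Myh3 fell from 14899 ± 348 to 6625 ± 230 CPM (SD, n = 3; log2 fold change -1.17, SE 0.05, adjusted p = 1.59e-18), and the fast chain Myh1 fell by 1.15 on the log2 scale (SE 0.05, adjusted p = 2.18e-18). The perinatal chain Myh8 fell by 0.16, and the slow chain Myh7 stood at -0.05 (adjusted p = 0.455). Myosin chains are close paralogs, and reads that mapped to several of them were not counted, so their levels are uncertain. Outside myosin, Myl1 fell by 0.78 and the skeletal actin Acta1 by 0.74 on the log2 scale, while Tmod4, which caps thin filaments, rose by 0.79.

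**Figure D3:**
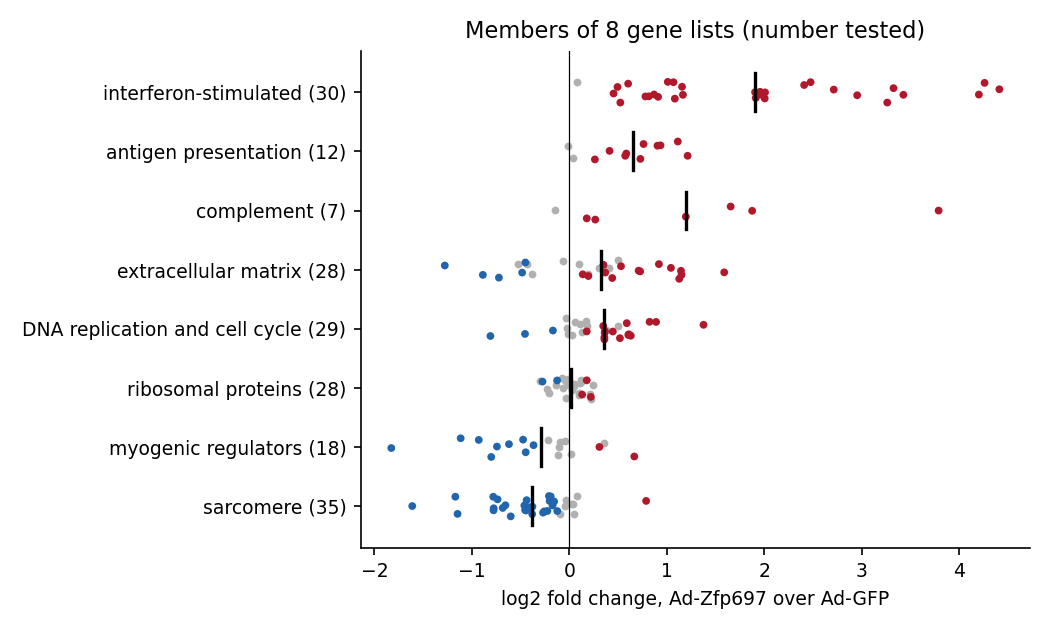
Log2 fold change, Ad-Zfp697 over Ad-GFP, of each tested member of 8 gene lists fixed beforehand, with the number tested in parentheses. Red and blue points are genes called higher and lower, grey points genes not called, and black bars list medians, which run from 1.91 for interferon-stimulated genes to -0.38 for sarcomere genes.

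In the list of myogenic transcription factors and fusion factors 9 of 18 fell and 2 rose (10 and 2 adjusted over the list alone), with a median log2 fold change of -0.29. Myog fell from 487 ± 18.7 to 225 ± 10.5 CPM (SD, n = 3; log2 fold change -1.11, SE 0.05, adjusted p = 1.17e-17). Myod1, which commits cells to the muscle lineage, fell by 0.74 on the log2 scale. Pax7, the marker of satellite cells, fell from 8.77 ± 0.329 to 2.50 ± 0.358 CPM (SD, n = 3). The members that rose were Jam2 (0.67) and Mymx (0.31), the latter a membrane protein needed for myoblast fusion. The list passed camera (adjusted p = 0.0186; adjusted p = 0.462 with an estimated correlation). Markers of undifferentiated satellite cells and myoblasts, which share Pax7, Myod1, Myf5 and Cdh15 with this list, moved alongside it: 8 of 14 fell and 2 rose (9 and 2 adjusted over the list alone; list adjusted p = 0.0791), including Spry1 at -0.97 and the Notch target Hes1 at -0.89. In excitation-contraction coupling and calcium handling 12 of 22 fell and 6 rose (the same adjusted over the list alone), with Stac3 at -0.94, Casq1 at -0.56 and Cacng1 at 0.54 (list adjusted p = 0.362). Among genes of the neuromuscular junction and of denervation 9 of 18 fell and 6 rose (the same adjusted over the list alone; list adjusted p = 0.575), with Colq, which anchors acetylcholinesterase at the junction, at 0.64 and Ncam1 at -0.43.

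In the list of DNA replication and the cell cycle 15 of 29 rose and 3 fell, likewise adjusted over the list alone, with a median log2 fold change of 0.36. Most mitotic members were not called: Cdk1 (-0.03), Ccnb2 (0.13), Aurka (-0.01), Aurkb (0.50), Plk1 (0.38), Bub1 (-0.03), Tpx2 (0.18) and Birc5 (0.18). Bub1b (0.63) and the proliferation marker Mki67 (0.36) rose. The risers included Mcm6 (0.61, SE 0.06, adjusted p = 2.04e-10) and Mcm4 (0.52) of the replicative helicase, Rrm2 (0.59), a subunit of the enzyme that makes deoxyribonucleotides, Ccne1 (0.61), which drives entry into S phase, and Cdt1 (0.82), which licenses origins. The genes that fell were Kif11 (-0.81), Top2a (-0.45) and Rrm1 (-0.17), the first a mitotic motor. The list passed camera (adjusted p = 0.0186; adjusted p = 0.462 with an estimated correlation). Replication-dependent histone genes, whose transcripts mostly lack poly(A) tails and so enter such libraries poorly, did not pass as a list: 6 of 12 rose and 1 fell (the same adjusted over the list alone; list adjusted p = 0.0828). Of 22 targets of p53 10 rose and 5 fell (11 and 5 adjusted over the list alone; list adjusted p = 0.362), with the death receptor Fas at 1.33 and Bax at 0.42.

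Matrix genes moved in both directions. Of 28 matrix components and crosslinkers 14 rose and 5 fell (the same adjusted over the list alone; list adjusted p = 0.173). The basement membrane linker Nid1 rose from 111 ± 3.69 to 247 ± 15.5 CPM (SD, n = 3; log2 fold change 1.15, SE 0.05, adjusted p = 1.70e-17), Col12a1 rose by 1.13 and Col3a1 by 0.92 on the log2 scale, and Thbs1 fell by 0.89. Among 18 matrix proteases and inhibitors 10 rose and 4 fell (the same adjusted over the list alone; list adjusted p = 0.362): Adamts9 rose by 1.69 and the membrane-bound protease Mmp14 by 0.65 on the log2 scale, while Adamts1 fell by 1.03. Components and targets of TGF-beta signalling split into 6 higher and 7 lower of 18 (7 and 7 adjusted over the list alone; list adjusted p = 0.517), with Tgfb2 at -0.74 and Tgfb3 at -0.62. Of 25 growth factors and myokines 6 rose and 6 fell (the same adjusted over the list alone; list adjusted p = 0.894). Fst, an inhibitor of myostatin and activins, fell from 260 ± 10.1 to 110 ± 9.10 CPM (SD, n = 3), Gdf11 fell by 1.28 on the log2 scale, and Fgf2 rose by 1.36. Camera pointed down and the median was -0.05, while the mean was 0.14.

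Transcripts described as targets of the muscle microRNAs miR-1 and miR-206 did not move one way: 6 of 21 rose and 6 fell (the same adjusted over the list alone; list adjusted p = 0.933). Pax7 (-1.83) and Notch3 (-1.21) fell, and Timp3 (1.15) and G6pdx (0.56) rose. Their median log2 fold change was 0.05 and their mean -0.04, with camera pointing up.

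No list of energy metabolism passed camera. Of 32 nuclear-encoded subunits of the respiratory chain 6 rose and 8 fell (5 and 8 adjusted over the list alone), with a median log2 fold change of -0.02 (list adjusted p = 0.879). Corresponding counts were 7 and 6 of 26 in the tricarboxylic acid cycle and fatty acid oxidation (7 and 5 adjusted over the list alone; list adjusted p = 0.845), 10 and 6 of 22 in glucose uptake and glycolysis (likewise adjusted over the list alone; list adjusted p = 0.667), and 4 and 2 of 9 in the pentose phosphate pathway (likewise adjusted over the list alone; list adjusted p = 0.839). In the pentose phosphate list the median was -0.04 and the mean 0.10, with camera pointing up. The lactate exporter Slc16a3 rose by 0.94 and hexokinase Hk2 by 0.45 on the log2 scale. Cholesterol synthesis had 10 of 24 members higher and 3 lower (likewise adjusted over the list alone; list adjusted p = 0.228), with Hsd17b7 at 0.96 and Fdft1, which makes squalene, at 0.92.

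Mitochondrial transcripts made up 4.01% to 4.10% of reads with Ad-GFP and 3.46% to 3.90% with Ad-Zfp697. Of 15 listed genes of the mitochondrial genome 9 could be tested and 7 fell (8 adjusted over the list alone), led by mt-Rnr2 at -0.41. The list had an adjusted p of 0.0681, and of 0.0163 without Ad-Zfp697 replicate 1. The remaining 6, mt-Co2, mt-Co3, mt-Atp6, mt-Atp8, mt-Nd3 and mt-Nd4l, had at most 2 counts over all 6 libraries. Of their bases, 99.0% to 100% in mt-Co2, mt-Co3, mt-Atp6, mt-Nd3 and mt-Nd4l matched transcripts annotated elsewhere in the genome, and their levels are uncertain because multi-mapped reads were not counted. The match covered only 21.1% of mt-Atp8, and mt-Co1, matched over 100%, still had 1432100 counts over the 6 libraries.

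Stress and turnover programmes showed members on both sides. In the lists of protein breakdown and FoxO targets 10 of 19 rose and 5 fell (list adjusted p = 0.413), and in lysosome and autophagy 11 of 22 rose and 7 fell (list adjusted p = 0.362), in both cases the same adjusted over the list alone. Fbxo30, a ubiquitin ligase, fell by 1.11 on the log2 scale, and Map1lc3b, the autophagosome protein LC3B, rose by 0.70. Of the unfolded protein response 5 of 19 rose and 2 fell, of the integrated stress response 8 of 20 rose and 5 fell, and of cytosolic heat shock chaperones 6 of 15 rose and 3 fell (each the same adjusted over the list alone; list adjusted p = 0.413, 0.745 and 0.517). Hyou1 rose by 0.72 and Gdf15 by 0.78, while Hspb8 fell by 0.47. Antioxidant genes controlled by NRF2 had 4 of 16 higher and 5 lower (5 and 5 adjusted over the list alone; list adjusted p = 0.845), with Srxn1 at -0.65. Targets of hypoxia-inducible factor had 8 of 18 higher and 5 lower (likewise adjusted over the list alone; list adjusted p = 0.839; median -0.05, mean 0.23 and camera pointing up), with Egln3 at 0.98. Immediate early genes had 6 of 20 higher and 7 lower (7 and 7 adjusted over the list alone; list adjusted p = 0.879), with Egr1 at -1.10, a median of 0.08, a mean of -0.02 and camera pointing down. Ribosome biogenesis had 7 of 22 higher and 4 lower (likewise adjusted over the list alone; list adjusted p = 0.789). Of 28 ribosomal proteins 3 rose and 2 fell in edgeR over all genes and 0 adjusted over the list alone; 8 had an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0 adjusted over the list alone (list adjusted p = 0.879). The calls over all genes were lost by Rpl23 without Ad-GFP replicate 3 (adjusted p = 0.229), Rpl8 without Ad-GFP replicate 2 (adjusted p = 0.25) and Rpl10a without Ad-Zfp697 replicate 1 (adjusted p = 0.144), among other libraries.

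No list of markers of other cell types passed camera. Of 9 tested markers of fibroblasts and fibro-adipogenic progenitors 1 rose and 1 fell (list adjusted p = 0.984), of 10 endothelial and mural markers 4 rose and 3 fell (0.879), of 6 Schwann and neural markers 3 rose and 2 fell (0.894), each the same adjusted over the list alone. Among 3 tested adipocyte markers 2 rose and 1 fell, likewise adjusted over the list alone, too few for the list test. Camera pointed down for the fibroblast list (median 0.09, mean 0.07) and the Schwann list (median 0.31, mean 0.20). Calls were lost by Lpl without Ad-GFP replicate 3 (adjusted p = 0.0511), Pdgfrb without Ad-GFP replicate 2 (adjusted p = 0.0583) and S100b without Ad-Zfp697 replicate 1 (adjusted p = 0.0579). Examples were Pdgfra at -0.63 and Pdgfrb at 1.12 in the fibroblast list, Cspg4 at -0.67 and Tek at 1.02 in the endothelial and mural list, Erbb3 at -0.84 and Foxd3 at 1.43 in the Schwann and neural list, and Cebpa at 1.19 and Pparg at -0.91 in the adipocyte list.

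Several of the largest changes fell outside these groups. Among called genes with a mean log2 CPM of at least 1, no overlap between the groups and a symbol admitted by the naming rule, the largest rises after Zfp697 and Iigp1 were of Pld4 (3.58), Macc1 (3.28), the adenylate kinase Ak7 (3.06), Pcp4l1 (2.90), the calcium channel subunit Cacnb4 (2.79), the interferon-induced GTPase Gbp7 (2.71), Spata13 (2.67) and the water channel Aqp5 (2.65), all at or below 1.67 CPM with Ad-GFP apart from Iigp1. As a gauge of background reads at scarce genes, the summed CPM of olfactory and vomeronasal receptor genes other than Vmn1r43 was 32.2 ± 1.91 with Ad-GFP and 43.5 ± 1.75 with Ad-Zfp697 (SD, n = 3), a ratio of 1.35. The ratio was 2.33 with Vmn1r43, which by itself went from 20.9 to 80.4 CPM. Vmn1r42 stayed in the sum behind the 1.35 and weighs on it. It held 7.29% of all receptor counts with Ad-GFP and 10.4% with Ad-Zfp697. Within the same limits, the largest falls after Ckm were of Mtus2 (-3.40), Adat2 (-3.19), the adhesion protein Cntnap2 (-2.90), B3galt5 (-2.68), Foxo6os (-2.51), the collagen Col5a3 (-2.49), Sbk2 (-2.43), Npy4r (-2.21) and Pabpn1l (-2.18). Scarcer genes below that limit had larger fitted changes, such as Ifi44 at 4.41 and Gbp3 at 4.26. Mtus2 fell from 31.5 ± 0.0976 to 2.95 ± 0.345 CPM (SD, n = 3). Reads were counted without regard to strand, and those over several genes were not counted. Reads of Foxo6os in exons shared with a gene on the other strand would be lost. Reads of the other strand outside the annotated exons of such a gene would count as Foxo6os.

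Adat2, a subunit of the enzyme that edits adenosine to inosine in the anticodon of transfer RNAs, fell from 6.26 ± 0.428 to 0.686 ± 0.00691 CPM (SD, n = 3; SE 0.18, adjusted p = 7.15e-15). It lies on chromosome 10 from 13552894 to 13563376 on the plus strand of GRCm38. Its neighbour on the other strand, Pex3, a peroxisome assembly factor at 13523842 to 13553142 that was singled out after its values were seen, fell from 29.7 ± 1.81 to 7.38 ± 0.284 CPM (SD, n = 3; log2 fold change -2.01, adjusted p = 3.10e-18). The genes share 249 exonic bases, 17.0% of those of Adat2 and 5.25% of those of Pex3. The 10 tested genes on each side had a median log2 fold change of -0.05.

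**Figure D4:**
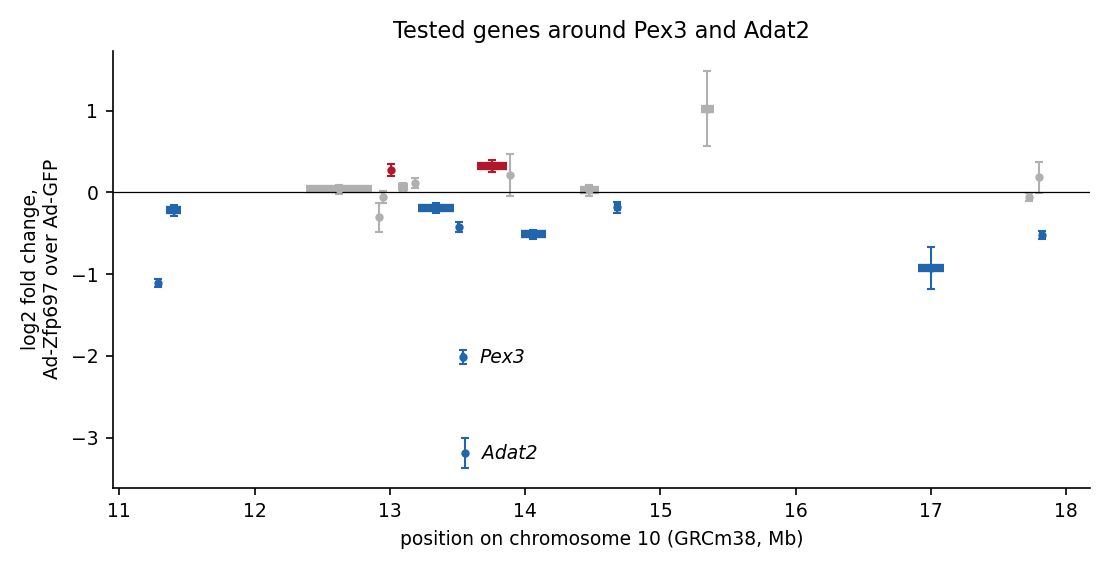
Log2 fold change, Ad-Zfp697 over Ad-GFP, against position on chromosome 10 (GRCm38, Mb) for Pex3, Adat2 and the 10 tested genes on each side; horizontal bars are gene spans, vertical bars standard errors, and blue, red and grey mark genes called lower, called higher and not called. Pex3 (-2.01) and Adat2 (-3.19) lie below the other 20 genes, whose values run from -1.11 to 1.03.

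The authors' deposited table of the same comparison lists 28958 genes, 7552 of them with an adjusted p under 0.05 (3802 higher, 3750 lower). Of these, 7329 were also called by edgeR and 0 of those had the opposite sign. Across the 16116 genes in both, Pearson's r between the log2 fold changes in the authors' deposited table and those of edgeR was 0.95. The authors' deposited table gives 9.46 for Zfp697, 4.16 for Iigp1, -3.71 for Ckm and -1.62 for Myh2.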

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

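All alternatives were listed before the data were examined. The number of called genes ran from 7560 with DESeq2 to 9236 with no filter on low counts, against 8865, and from 7919 to 8733 when a library was left out; 0 genes called in both changed sign under any alternative. Scaling by library totals alone gave 5115 higher and 3661 lower genes and moved the median of all genes by 0.05 on the log2 scale. Of genes changed at least 2-fold, 1544 rose and 749 fell with no filter on low counts, and 422 rose and 294 fell with at least 50 counts in 3 libraries, against 1025 and 577; the filter removes or adds the scarce genes in which most such changes lay. Of 169 named genes 165 were called, and 156 kept call and direction under every alternative that tested them; the exceptions include 4 ribosomal proteins. With an estimated correlation camera called 0 lists: the adjusted p was 0.462 for interferon-stimulated genes, antigen presentation, myogenic regulators and DNA replication, and 0.491 for the sarcomere. Correlation alone does not account for this loss. For myogenic regulators the estimate, 0.00803, lay under the preset 0.01, yet camera's unadjusted p went from 0.00245 to 0.0372. The setting with an estimated correlation has only 4 residual degrees of freedom. The other called lists had estimates above the preset: 0.0209 for DNA replication, 0.0611 for antigen presentation, 0.115 for interferon-stimulated genes and 0.209 for the sarcomere. Where such estimates hold, camera's p-values under the preset are too small. For the sarcomere camera's unadjusted p went from 7.05e-08 to 0.0934. The fry test asks whether a list moves by itself and not against other genes. As 55.0% of all tested genes were called, a list can pass it without standing out from the rest. Fry called 29 lists. Of those that camera had not called, its adjusted p was 0.000270 for myoblast markers, 0.000416 for cytokines and for cholesterol synthesis, 0.00132 for p53 targets, 0.00134 for matrix proteases, 0.00136 for complement, 0.00182 for protein breakdown, 0.00251 for histones, 0.00324 for macrophage markers, 0.00384 for autophagy, 0.00450 for matrix, 0.00466 for ribosome biogenesis and for TGF-beta, 0.00498 for hypoxia, 0.00730 for calcium handling, 0.0132 for Schwann markers, 0.0164 for the unfolded protein response, 0.0181 for the pentose phosphate pathway, 0.01845 for NF-kB, 0.0204 for mitochondrial transcripts, 0.0337 for the integrated stress response, 0.0354 for glycolysis, 0.0465 for heat shock and 0.0488 for the neuromuscular junction. Among these lists fry pointed down for myoblast markers, TGF-beta, calcium handling, Schwann markers, mitochondrial transcripts and the neuromuscular junction, and up for the rest. Its direction went against the median log2 fold change for Schwann markers (median 0.31), hypoxia (-0.05) and the pentose phosphate pathway (-0.04). A fry call therefore need not mean that most members moved its way. Leaving out each library called 5 or 6 lists, with adjusted p from 0.0458 (without Ad-GFP replicate 2) to 0.121 for macrophage markers and from 0.0163 (without Ad-Zfp697 replicate 1) to 0.112 for mitochondrial transcripts. The cause was not tested.

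Libraries with the same replicate number did not deviate together (correlations of -0.0004, 0.001 and -0.02), so the numbers were not taken as pairs. With a replicate block 8816 genes and 5 lists were called. The simulation recovered 66.0% of genes lowered 1.5-fold and 78% of those raised 1.5-fold. It changed far fewer genes than were called in the data, so these shares do not measure the power of the real comparison.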

Other observations

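Beyond the lists, 28 gene families defined by their symbols were tested by camera after the values had been seen, and 2 were called; thymosins, with too few genes, were left out. The beta protocadherins, neuronal adhesion molecules encoded side by side on chromosome 18 (37300799 to 37524479, GRCm38), had 11 of 12 tested members lower and a median log2 fold change of -0.91 (adjusted p = 0.000710; adjusted p = 0.362 with an estimated correlation), with Pcdhb16 going from 13.8 ± 0.996 to 6.17 ± 0.5 CPM (SD, n = 3). Their close sequence means that multi-mapped reads were lost, so single members are uncertain. Numbered zinc finger genes, Zfp697 left out, had 163 of 350 lower and 47 higher, with a median of -0.21 (adjusted p = 8.35e-05; adjusted p = 0.539 with an estimated correlation), and the median was -0.17 with library totals alone. Zfp629 fell by 1.86 and Zfp365 by 1.21 on the log2 scale. With an estimated correlation 0 families were called, and 2 had an unadjusted p under 0.05. The gamma protocadherins next to the beta cluster had 7 of 21 higher and 4 lower.

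Several long noncoding RNAs of muscle also fell, a group picked after its values were seen and not tested as one. Lincmd1, which arises from the locus of miR-206 and miR-133b, fell from 998 ± 22.3 to 339 ± 16.9 CPM (SD, n = 3; log2 fold change -1.56, adjusted p = 4.98e-21 in edgeR; -1.57 in the authors' deposited table). H19 fell from 17322 ± 339 to 10742 ± 335 CPM (SD, n = 3; -0.69, adjusted p = 1.98e-13) and Neat1, the scaffold of paraspeckles, from 426 ± 7.19 to 158 ± 19.3 CPM (SD, n = 3; -1.43, adjusted p = 8.69e-13). Meg3, Rian and Mirg, which share an imprinted locus, had log2 fold changes of -0.58, -0.50 and -0.61 (adjusted p = 0.0150, 1.68e-05 and 4.89e-06). In the opposite direction Foxa1, a transcription factor of endodermal tissues, rose from 0.415 ± 0.150 to 4.01 ± 0.783 CPM (SD, n = 3; adjusted p = 6.17e-12).

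In what follows, the tests of leukocytes, of virus preparations, of shared reads (its bound was rewritten once the overlap was known) of background in 5 gene classes and of receptor genes without Vmn1r43 were chosen only after the results were seen. The test of like abundance was set once the number of pairs was known, and the comparison of interferon CPM between groups once the counts were. The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. By edgeR the real split called 8865 genes and the highest other 0 (178 at an unadjusted p under 0.05, and 0 by DESeq2 and by limma-voom); 1 of the 10 splits, the real one, gave as many. The real split called 5 lists and the highest other 5, so that 2 of the 10 splits gave as many. Camera called the interferon list in every split, with adjusted p from 1.74e-05 to 0.0111 in the others. All other splits mixed both viruses unevenly on each side. That leaves part of their difference between the sides and widens the spread within them. Nothing is therefore concluded from the splits, for genes or for lists.

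Interferon-stimulated genes rose with Zfp697, and in the macrophage list fixed beforehand 5 of 7 tested markers rose too, with a median log2 fold change of 1.84 (Cd74 2.24, Cd68 1.84), and Mrc1 went from 18.1 to 30.3 CPM. Leukocytes in those cultures would bring their abundant transcripts, but the median gain of 9 leukocyte genes was 0 CPM, a ratio of 0 to the median gain of 3.14 CPM of the interferon list, and 8 of the 9 stayed under 0.5 CPM in every Ad-Zfp697 library; the exception, Laptm5, went from 2.61 to 2.09 CPM. Interferon transcripts made by the cultures remain a candidate source: 18 interferon genes together had 4, 7 and 16 counts in the Ad-Zfp697 libraries and 2, 1 and 4 in the Ad-GFP libraries, near the floor of 3 counts and with Ifnb1 at 0 in every library. Scaled to depth these were 0.137 to 0.494 CPM with Ad-Zfp697 and 0.0363 to 0.114 CPM with Ad-GFP, without overlap. A difference between the 2 virus preparations cannot be told apart from an effect of Zfp697, because 0 libraries of another preparation, another dose or no virus were analysed here, and the response may come from either. The same limit holds for every other change between the groups.

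Genes that fell lay side by side more often than chance gives, and so did genes that rose. Side by side here means next to each other among the tested genes of a chromosome, at any distance. In 58 adjacent tested pairs both genes fell at least 2-fold, above the mean of 20.6 and the highest value of 39 in 10000 random orders (permutation p = 0.0001, the smallest they can give). In 110 pairs both rose, against a mean of 65.1 and a highest value of 93 (permutation p = 0.0001). Like abundance of neighbours does not account for either. Drawing the falls among genes of like abundance gave a 95th percentile of 28 pairs and a highest value of 39, and drawing the rises a highest value of 98. Pex3 and Adat2 were the pair with the lowest sum of log2 fold changes. There, loss of a stretch covering most of the 20 flanking genes is argued against by their median log2 fold change of -0.054. Of these flanking genes 8 fell and 2 rose (lowest -1.11). They run from 11281330 to 17845665, so a loss limited to the pair or its nearest neighbours would leave this median near 0 and was not tested. Shared reads are argued against by an overlap of at most 17.0% of the exonic bases beside falls of 75.2% and 89.0%. Shared regulation of neighbours is a candidate explanation that was not tested. Reads running from one gene into the next stay open for the 28 pairs on the same strand and the 14 convergent pairs. Gaps among these differed widely, such as 2 bases at Pter and C1ql3 and 628575 at 4933404I11Rik and Vstm2b. Pairs were not separated by distance. In the 16 divergent pairs transcripts run away from each other, which argues against such reads where the spans do not overlap. Some divergent pairs overlap at their starts, Pex3 and Adat2 among them, so each transcript begins inside the other gene. The spans of 48 of the 58 pairs do not overlap, but such reads can pass the annotated ends.

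Scarce genes rose more often than they fell. In the lowest of 4 abundance classes of 4029 genes each, 673 genes rose at least 2-fold and 330 fell, while in the highest 13 rose and 37 fell; rises made up at least 66.8% of such changes in the lowest class under 3 other scalings, but none of these lowered the fold changes enough to test scaling as the cause, which stays open. The bound set beforehand for genomic DNA or another diffuse background used olfactory and vomeronasal receptor genes. Their sum had to be at least 1.5 times higher with Zfp697. The sum was 2.33 times higher. Vmn1r43 gave 64.8% of those counts with Ad-Zfp697, and without it the ratio was 1.35, short of the bound though without overlap. Vmn1r42 gave a further 10.4% with Ad-Zfp697 against 7.29% with Ad-GFP, and the ratio without both was not computed. In the later test, among genes under 0.5 CPM the summed CPM rose 1.36 times for protein-coding genes, 1.36 for receptors and 1.40 for processed pseudogenes (189 ± 1.38 against 265 ± 73.4 CPM; SD, n = 3, so unevenly between the Ad-Zfp697 libraries), but 1.03 for lncRNA and 0.944 for unverified transcripts (TEC), with overlapping groups in the last pair. Since real falls of lncRNA and TEC genes may hide a background there, neither test decides and background stays open; a low-level rise of otherwise silent genes with Zfp697 or with its virus preparation was not tested.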
